A study of Drosophila melanogaster with 6 samples.

How the data were processed

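Transcript levels were measured in ovaries of Drosophila melanogaster on 6 one-colour oligonucleotide arrays with biotin-labelled RNA. The samples were 3 of bam[delta86] mutants and 3 of flies also mutant for stwl, called stwl bam here. The labels name the ovary as source and the series text speaks of germ cells of the ovary, so how far somatic tissue was removed is not given in the sources used here. Group and replicate number came from each sample's labels. Nothing in the labels says that the samples came from separate crosses or dissections, so p-values measure the spread between these samples, which may be technical.

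The deposited values are linear intensities, 1 per probe set and array. They were made with GCOS per the submitters' processing notes, and its version and settings are not given in the sources used here. The 2% to 98% trimmed mean intensity was 250.0 on 5 arrays and 220.5 on bam replicate 1. The trimmed means thus differed by more than 5%, and the rule fixed before the data were examined then called for quantile normalization. That was done over all probe sets except the 183 control sets. Log2 was taken after adding an offset of 7.9, the 25th percentile of all deposited intensities, so fold changes of dim genes are understated. A probe set was kept if it reached the 40th percentile of its own array on at least 3 of the 6 arrays, which left 11477. No pair of arrays held the same values. Detection calls were not used here.

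Of 18952 probe sets, 13647 were paired with 1 gene, 402 with several and 4720 with none in the annotation table used here. Through gene numbers, 13544 of the 13647 matched a RefSeq gene table of the Release 6 assembly and 103 kept the symbol of the annotation. The array files name no assembly, so no coordinates are printed. A gene was represented by its probe set with the highest mean, and 8764 genes were tested. Probe sets with several genes or none stayed in the fit and are counted apart.

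The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. The 28 gene lists fixed before the data were examined were tested with limma's camera at its preset correlation of 0.01, adjusted over the 26 lists with at least 5 tested genes. The histone list and the transposable element list fell below that number. Members were also counted adjusted over the list alone. Named genes are stwl and bam, then the 12 largest rises and 12 largest falls among genes that passed and whose arrays of one genotype all lay beyond those of the other. Genes known only by a CG number were passed over there, 17 among the rises and 7 among the falls. From each list up to 4 passing members with the largest change are named, or up to 2 with the smallest p where none passed. Further genes named outside this rule were chosen after their values were seen, and are marked so.

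Background was taken per array as the 95th percentile of 44 control probe sets for bacterial and tag sequences that flies lack, a choice made after seeing the data. It lay between 13.5 and 38.8 in intensity. A gene below it on all 3 arrays of a genotype is given as "at least" a fold, against the higher of the background and its own value on each array. For a gene below it on some arrays of a genotype the number of these arrays is given, mostly with the fold after setting them to background, an alternative chosen after seeing the data. Where leaving out an array puts all remaining arrays of a genotype below it, a bound is given in the same way, also added after seeing the data. The number of arrays, 3 per genotype, limits the precision.

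The fit was tested on simulated arrays with the 8764 genes' own means and spreads and 200 changed genes. It recovered 88.2% of genes changed by 2 on the log2 scale, 57.3% at 1 and 20.9% at 0.5, and 4.7% of calls were false. The simulated noise was independent between genes, and far fewer genes were changed than the 24.1% called in the data. These shares therefore need not hold for the data, and they do not cover differences in RNA quality between the genotypes. Alternatives changed the normalization, offset, filter, prior, array weights, replicate block, test, probe set rule, threshold and list correlation, and left out each array in turn. The 3' and middle control changes have 95% t intervals on the rescaled and on the quantile scale. Added after seeing the data were a rescaling to 1 trimmed mean, a block for replicate 1 against replicates 2 and 3, a fit on replicates 2 and 3 only, and the estimated correlation under alternatives that called a further list.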

Results

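The arrays compared ovaries of bam mutants with ovaries of stwl bam mutants, with 3 samples of each genotype. The bam gene is needed for germline stem cell daughters to differentiate, and ovaries without it fill with undifferentiated germ cells. The stwl gene encodes Stonewall, a DNA-associated protein needed to maintain germline stem cells. The comparison asks which transcripts differ when stwl is also mutated in germ cells that cannot differentiate. Median intensities of the arrays ran from 26.1 to 39.8, and between 50.8% and 64.5% of probe sets lay above the background of their array.

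Among single genes, the ribosomal protein paralogue RpL22-like, the germline genes tut and blanks, the muscle genes Act88F and up, and the immune peptide genes BomBc2 and Drs were higher in stwl bam ovaries. The genes ush, crq, eya and kis were among the lower ones. Of the 26 gene lists tested with camera in limma, 1 was called at a preset correlation and none with an estimated one, where that list had a limma adjusted p of 0.859. RpL22-like rose by 3.40 ± 0.14 (SE) on the log2 scale, from 8.83 ± 0.06 to 12.23 ± 0.30 (SD, n = 3). Of the 8764 genes tested with limma, 974 were higher and 1142 were lower in stwl bam. At least 2-fold changes were found for 265 of the higher and 194 of the lower genes. The arrays of the genotypes did not overlap for 42.7% of all tested genes, where chance gives 10%. Leaving out 1 array lowered these counts by over 1.5 times in several cases: 516 higher and 557 lower genes were called without bam replicate 1, 644 and 680 without bam replicate 3, and 591 and 708 without stwl bam replicate 3. Without bam replicate 2, 751 lower genes were called. Of the 100 named genes that passed, 34 lost their call when some single array was left out, and they are given with each group. With a plain test that does not pool across genes, 60 of the 100 lost their call. With intensities as deposited, which leave bam replicate 1 at a lower trimmed mean, 967 higher and 776 lower genes were called, so the larger side turns round. It did not turn with median centring (926 higher and 1207 lower) or rescaling to 1 trimmed mean (994 and 1121). With deposited intensities or under either of these normalizations 13 named genes lost their call.

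RNA quality controls moved with genotype. The ratio of 5' to 3' signal of the actin control was 0.149 ± 0.03 (SD, n = 3) in bam and 0.606 ± 0.077 in stwl bam. For eIF-4a it was 0.094 ± 0.014 against 0.429 ± 0.017, and for GAPDH 0.138 ± 0.014 against 0.335 ± 0.067. All 3 stwl bam arrays lay above all 3 bam arrays for each control, and an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1. This difference stands beside every gene group described here. Control intensities are given with the arrays rescaled to 1 trimmed mean.

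**Figure D1:**
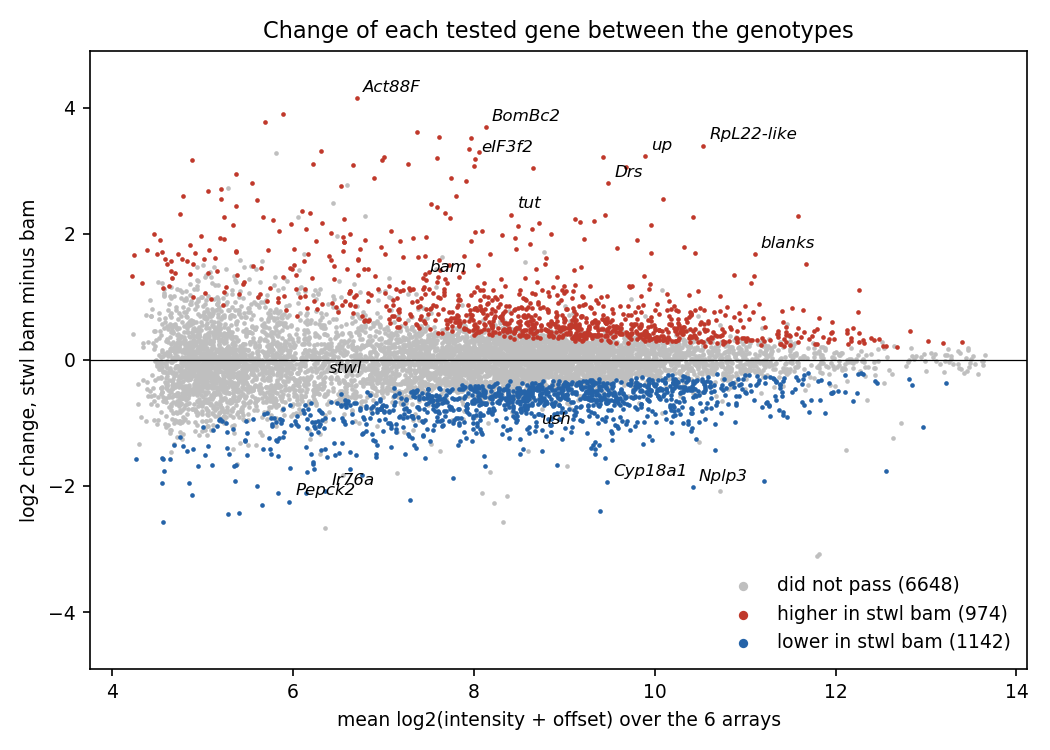
Log2 change (stwl bam minus bam) of each of the 8764 tested genes against its mean log2 intensity over the 6 arrays. Red points are the 974 higher and blue points the 1142 lower genes at an adjusted p under 0.05 in limma, grey points did not pass, and RpL22-like lies at 3.40.

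The stwl transcript itself did not differ detectably. Its log2 level was 6.48 ± 0.15 (SD, n = 3) in bam and 6.17 ± 0.38 in stwl bam, a change of -0.31 with a limma adjusted p of 0.396. The part of the transcript that its probe set covers, and what the allele does to that part, are not known here, so the value does not check the labels. The same holds for the bam probe set and its deletion allele. The bam signal, from an allele that both genotypes carry, rose by 1.29 ± 0.26 (SE), from 6.79 ± 0.04 to 8.09 ± 0.57 (SD, n = 3), with a limma adjusted p of 0.00935.

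Of 12 tested germline differentiation genes, 4 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone. tut, which encodes a partner of Bam in translational repression, rose by 2.30 ± 0.11 (SE), from 7.26 ± 0.09 to 9.57 ± 0.09 (SD, n = 3). blanks, which encodes a double-stranded RNA binding protein, rose by 1.68 ± 0.10 and Rbp9 by 0.49 ± 0.14, and egl fell by 0.60 ± 0.12. The limma adjusted p of tut was 1.31e-05. As a list they were not called by camera (adjusted p = 0.559 in limma). Of 13 germ cell genes 1 rose and 3 fell, also adjusted over the list alone. tud was higher by 0.62, while pum changed by -0.94, ovo by -0.84 and otu by -0.67. Another probe set of pum rose by 0.80. The call of Rbp9 was lost without any of the arrays except stwl bam replicate 2, and that of otu without bam replicate 1 or 2.

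Of 38 ribosomal protein genes 7 rose and 1 fell, and 30 did not pass, with the same counts adjusted over the list alone. With intensities as deposited 4 rose and 1 fell. The largest changes among passing members were those of RpL22-like, RpL37-2 at 2.18 ± 0.17 (SE) and RpS10a at 1.05 ± 0.08, which rose, and RpS19b, which fell by 0.55 ± 0.12, a call lost without bam replicate 1. The list's camera adjusted p in limma was 0.303. It was 0.00423 with intensities as deposited, 0.00169 with median centring and 0.00193 with rescaling to 1 trimmed mean, so a call at the preset correlation depends on the normalization. With an estimated correlation the limma adjusted p was 0.859, and 0.940, 0.919 and 0.930 under these 3 normalizations, so the list was called under none of them. eIF3f2, a paralogue of a translation initiation factor subunit, rose by 3.19 ± 0.26 (SE).

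Of 34 testis and spermatogenesis genes 3 rose and 2 fell, also adjusted over the list alone. A further 41 members with a probe set fell below the filter, so the counts do not cover them. The risen genes tut, blanks, RpL37-2 and eIF3f2 were not members of this list. RpL22-like belongs to this list too. eIF4E3 rose by 1.18 ± 0.17 (SE) and Phf7, a chromatin reader that promotes male germline identity, by 0.92 ± 0.08, and topi fell by 1.23 ± 0.32, with 1 stwl bam array below background. Of 16 sex determination genes 2 rose and 3 fell, and adjusted over the list alone 2 rose and 4 fell. msl-2 fell by 1.38, with 1 stwl bam array below background, mof by 0.82 and chinmo by 0.64, beside the rise of Phf7. The call of topi was lost without any single bam array, and that of msl-2 without bam replicate 1, bam replicate 2 or stwl bam replicate 3 and with rescaling.

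**Figure D2:**
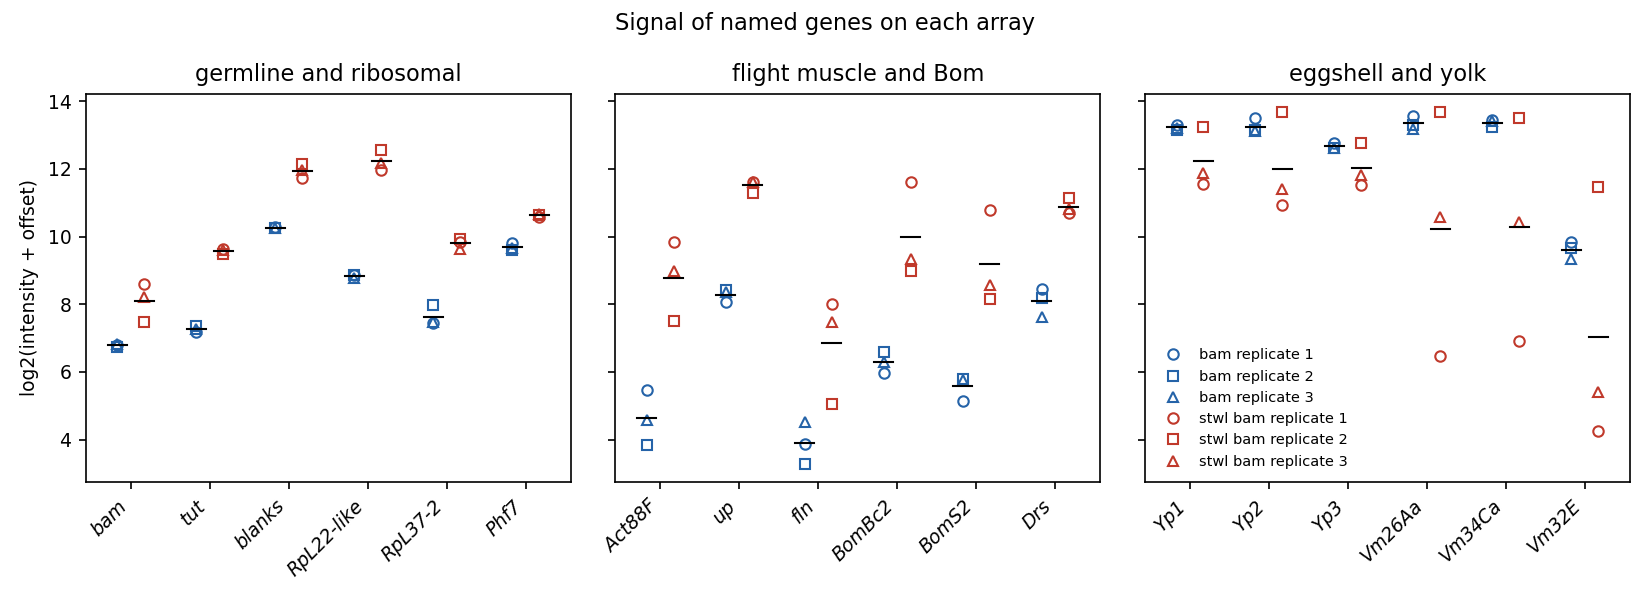
Log2(intensity + offset) of named genes on each array, with bam in blue, stwl bam in red, a symbol per replicate number and a line at each mean. tut lay near 7.26 on the bam arrays and 9.57 on the stwl bam arrays, while Vm26Aa, which like Yp2, Vm34Ca and Vm32E was chosen after its values were seen, was at 6.47 and 10.57 on stwl bam replicates 1 and 3 and at 13.67 on replicate 2.

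Muscle genes were among the 12 named rises, which were reached after passing over 17 genes known only by a CG number. Act88F, the flight muscle actin, rose by 4.14 ± 0.59 (SE), from 4.63 ± 0.82 to 8.78 ± 1.19 (SD, n = 3), and up, which encodes troponin T, by 3.23 ± 0.13. Act88F was below background on 2 of the 3 bam arrays, and with those set to background it was at least 10.8-fold higher. Without stwl bam replicate 2 its change was 4.78. fln, the flight muscle gene flightin, lay below background on all bam arrays and 1 stwl bam array and was at least 3.07-fold higher in stwl bam. Its call ended without bam replicate 1, bam replicate 2 or stwl bam replicate 3, and it was at least 2.04-fold higher without stwl bam replicate 1 and at least 5.73-fold without stwl bam replicate 2. Of 22 muscle genes 8 rose and 4 fell, and 5 fell adjusted over the list alone, while with intensities as deposited 5 rose and 2 fell. Mf rose by 1.11 and Obsc fell by 0.97, while another probe set of Mf was at -0.30. The call of Obsc was lost without bam replicate 2, bam replicate 3 or stwl bam replicate 3. The list was not called by camera (adjusted p = 0.443 in limma).

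Among the 12 named rises were 4 Bom genes, which encode short immune-induced peptides: BomBc2 rose by 3.69 ± 0.58 (SE), BomS2 by 3.61 ± 0.59, BomS6 by 3.53 ± 0.56 and BomT2 by 3.11 ± 0.46. Stwl bam replicate 1 carried part of these values: without it they were 2.88, 2.80, 2.81 and 2.49, still past the limma threshold, and a plain test without pooling across genes called none of the 4. Drs, an antifungal peptide gene, rose by 2.80 ± 0.21. In the antimicrobial and immune list 2 of 20 genes rose and 5 fell, and 3 rose and 5 fell adjusted over the list alone, while with intensities as deposited 4 rose and 3 fell. Def was 2.83-fold lower and Tl fell by 0.94, though another probe set of Tl was at 0.76. Of 16 fat body genes 3 rose and 1 fell, and 3 rose and 4 fell adjusted over the list alone. Obp99c rose by 3.51 ± 0.60, Tsf1, an iron transport protein gene, by 3.21 ± 0.35 and apolpp by 1.47 ± 0.23, and NLaz fell by 0.93. Without stwl bam replicate 1, Obp99c was at 2.84. The call of NLaz was lost without any single bam array or stwl bam replicate 3, and that of Def without bam replicate 2 or 3. Camera called neither list in limma (adjusted p = 0.758 and 0.721).

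Of 17 haemocyte genes 7 fell, 1 rose and 9 did not pass, and adjusted over the list alone 8 fell and 1 rose. ush, which encodes a GATA factor cofactor, fell by 1.12 ± 0.11 (SE), the scavenger receptor gene crq by 1.04 ± 0.13, PPO1 by 1.02 ± 0.21 and Sr-CI by 0.73 ± 0.13. It was the only one of the 26 lists that camera called (limma adjusted p = 0.0238), with a median change of -0.48. The call was lost with an estimated correlation, where the limma adjusted p was 0.859. It was also lost without bam replicate 3 and without stwl bam replicate 2, at limma adjusted p of 0.063 and 0.0822.

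Of 14 follicle cell genes 1 rose and 4 fell, and 2 rose and 6 fell adjusted over the list alone. Past1 rose by 1.70 ± 0.16 (SE), while Mmp2 fell by 1.18 ± 0.23, aos by 1.10 ± 0.17 and eya by 1.08 ± 0.15. None of 18 yolk, vitelline membrane and chorion genes passed in limma, either over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 3 of them were lower, and a plain test without pooling across genes called 0. The means of Yp1 and Yp3 were 2.01-fold and 1.55-fold lower in stwl bam, with limma adjusted p of 0.0777 and 0.117. Without stwl bam replicate 2 the list was called by camera (limma adjusted p = 0.000317), and with all arrays its adjusted p was 0.559. With an estimated correlation these limma adjusted p were 0.722 and 0.951. Of 10 ovarian somatic niche genes 1 fell, Lar by 0.89. Of 21 oocyte and maternal genes 1 rose and 4 fell, with mtrm at -1.32, tor at -0.96, trk at -0.94 and gnu at 0.64. The call of tor was lost without any of the arrays except stwl bam replicate 2, with intensities as deposited and with rescaling. The counts of the niche and the oocyte lists were the same adjusted over the list alone.

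Among chromatin and genome defence genes, 6 of 27 Polycomb and trithorax genes fell and 0 rose in limma. At an unadjusted p under 0.05, 9 were lower and 2 higher, and the plain test called 0. The larger falls were Jarid2 at -1.05, skd at -0.86, kis at -0.79 and osa at -0.71. Jarid2 lost its call without bam replicate 1, bam replicate 3 or stwl bam replicate 3, and skd without bam replicate 1. Of 30 piRNA pathway genes 2 rose and 7 fell, and 8 fell adjusted over the list alone. BoYb fell by 0.81, tapas by 0.56 and Panx by 0.45, beside the rise of tud. Panx lost its call without bam replicate 2, bam replicate 3 or stwl bam replicate 3, and with intensities as deposited, where 2 of the list rose and 4 fell. Of 27 heterochromatin genes 2 rose and 4 fell, with Cp190 at -0.86, Su(var)2-HP2 at -0.57, bon at -0.39 and HP1c at 0.49, while with intensities as deposited 1 rose and 1 fell, without Su(var)2-HP2 and bon. Su(var)2-HP2 lost its call without bam replicate 2, bam replicate 3 or stwl bam replicate 3, and bon without any array except bam replicate 2 and stwl bam replicate 1. Of 33 homeotic and Polycomb target genes 2 rose and 4 fell, with zen at -1.29 and esg at -1.18. cad was below background on 2 of the 3 stwl bam arrays and at least 2.11-fold lower there, a call lost without any single bam array or stwl bam replicate 3. knrl lay below background in bam and was at least 1.53-fold higher in stwl bam, a call lost without stwl bam replicate 3. The counts of the Polycomb and trithorax, heterochromatin and homeotic lists were the same adjusted over the list alone. For comparison, of all 8764 tested genes 974 were higher and 1142 lower. In the longest of 5 gene length groups 23.1% were lower, and list counts were not adjusted for length. Camera called none of these chromatin and genome defence lists in limma (adjusted p from 0.303 to 0.965), nor the others that follow.

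Of 24 DNA damage and apoptosis genes 1 rose and 6 fell, and 9 fell adjusted over the list alone, while with median centring 1 rose and 10 fell. skl, a cell death activator gene, rose by 1.10 ± 0.20 (SE), and tefu fell by 0.74, puc by 0.66 and egr by 0.64. Another probe set of egr was at -0.18 and did not pass, and tefu lost its call without bam replicate 2, bam replicate 3 or stwl bam replicate 3. Of 33 cell cycle and replication genes 2 rose and 5 fell, and 4 fell adjusted over the list alone. PCNA was at 0.41, CycB3 at -0.57, Cdk4 at -0.51 and Orc1 at -0.46, the last lost without any array except stwl bam replicate 2, and with intensities as deposited. Of 19 meiosis genes 2 rose and 2 fell, vilya and sunn at 0.49 and 0.45, hdm and c(2)M at -0.76 and -0.47, where hdm passed under none of the 3 other normalizations and c(2)M only with median centring. Each of these 4 calls was lost without any of 4 or 5 single arrays. In the BMP signalling list 3 of 16 genes fell, and 2 fell adjusted over the list alone. Smox, a gene of the related activin pathway that the list also held, fell by 0.84. Dad fell by 0.75 and sax by 0.33, the last lost without any of 4 single arrays, with intensities as deposited and with rescaling. In the heat shock list 2 of 9 genes fell, Hsc70-3 by 0.46 and Hsp27 by 0.38, and neither passed with intensities as deposited. Of 38 detoxification genes 1 rose and 4 fell. GstD5, below background in bam, was at least 2.02-fold higher, and GstE1 fell by 1.30, Cyp6a17 by 1.01 and Mdr65 by 0.90. With intensities as deposited 2 rose and 2 fell, without Mdr65. Leaving out single arrays ended the calls of GstD5 and Mdr65 for 2 arrays each, and of GstE1 and Cyp6a17 for 3 arrays each. The meiosis, heat shock and detoxification counts were the same adjusted over the list alone.

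Of 18 neuron genes 1 rose and 2 fell, and 1 fell adjusted over the list alone, while under each of the 3 other normalizations 2 rose and 1 fell, without futsch. futsch, below background on 2 of the 3 stwl bam arrays, was at least 1.76-fold lower, CASK fell by 0.68, and Sh, below background in bam, was at least 1.44-fold higher. Leaving out single arrays ended the calls of CASK and Sh for 3 arrays each and of futsch for 5. None of 12 gut and 5 male accessory gland genes passed in limma, also adjusted over the list alone. At an unadjusted p under 0.05 these were 0 and 1, and the plain test called 0. Jon74E was at -0.45 and Mal-A5 at 0.14. SP was at -0.43, with 1 bam and 2 stwl bam arrays below background. Acp29AB lay below background on all stwl bam arrays and 2 of the 3 bam arrays, so only a bound can be given, at least 1.17-fold lower in stwl bam and not past the threshold.

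The largest falls among named genes came from several classes. Ir76a, an ionotropic receptor gene, fell by 2.08 ± 0.18 (SE). Pepck2, a gluconeogenic enzyme gene, changed by -2.25 ± 0.37, with 2 of the 3 stwl bam arrays below background, and was at least 3.59-fold lower with those set to it. The neuropeptide-like precursor gene Nplp3 fell by 2.01 ± 0.25, from 11.43 ± 0.05 to 9.41 ± 0.60 (SD, n = 3). Cyp18a1, which encodes an ecdysteroid-inactivating enzyme, fell by 1.94 ± 0.17, while another of its probe sets was at -0.32 and did not pass. nwk and dpr8, also below background on 2 of the 3 stwl bam arrays, were at least 3.27-fold and 2.44-fold lower, and Cyp4d8 was at -1.88. stj and Gagr lay below background on all stwl bam arrays, Gagr also on 1 bam array, and were at least 2.09-fold and 1.55-fold lower there. The noncoding RNA gene pncr008:3L changed by -2.23 ± 0.66 (SE). Cyp6a14 and cDIP, below background on 2 of the 3 stwl bam arrays, were at least 3.28-fold and 2.54-fold lower. The calls of pncr008:3L and Cyp6a14 each ended when any of 5 arrays was left out, and that of cDIP for 4. Without stwl bam replicate 2 the change of pncr008:3L was -3.10, and Cyp6a14, then below background on all remaining stwl bam arrays, was at least 5.30-fold lower. The change of pncr008:3L was -1.53 without stwl bam replicate 1. That of Cyp6a14 was -1.48 without stwl bam replicate 3, with 1 remaining stwl bam array below background. Of the 24 genes with the largest changes, 14 did not pass the plain test.

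**Figure D3:**
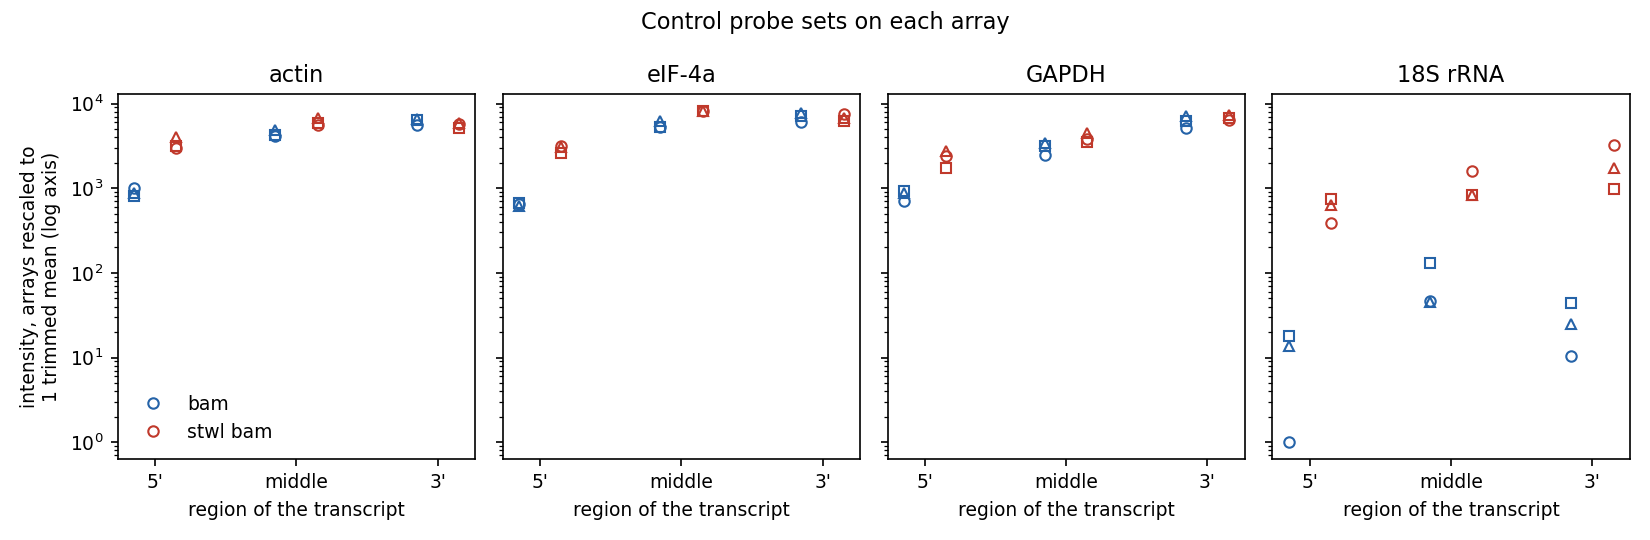
Intensity (log axis) of the 5', middle and 3' control probe sets of actin, eIF-4a, GAPDH and 18S rRNA on each array after rescaling to 1 trimmed mean, with bam in blue, stwl bam in red and a symbol per replicate number. The 3' sets of actin average 6172 in bam and 5575 in stwl bam, while the 5' sets average 907.3 and 3381.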

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

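The tests of replicate 1, of the fallen genes, of carried-over tissue and of the eggshell genes were chosen after the results were seen. The 18S rRNA control probe sets and the 5' to 3' control ratios, outside the gene comparison, lay above the bam level in stwl bam, while the 3' sets of actin and eIF-4a did not. The 18S rRNA sets averaged 591.3, 1083 and 1990 at the 5', middle and 3' regions in stwl bam, against 10.9, 73.8 and 26.2 in bam. The 5' over 3' ratios in stwl bam were 0.606 for actin, 0.429 for eIF-4a and 0.335 for GAPDH. Among probe sets with no gene name, 135 were higher and 152 lower in stwl bam by limma.

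The first pattern is the number of genes called by limma, 2116, while the highest of the other splits of the 6 arrays called 0 (at most 277 at an unadjusted p under 0.05, against 3341). The real split was 1 of 10 splits to call as many, and 10 splits are too few for a share under 0.05. Bacterial spike-in signal was lower on replicate 1 of both genotypes. Replicate 1 occurs once in each genotype, so a shift shared by its arrays cannot make a difference between the genotypes. Within replicates 2 and 3 alone limma called 1244 genes, which argues against that split as the cause of these calls. Of these, 97.7% had the same direction between the replicate 1 samples (74% of all genes did). Any difference tied to genotype, RNA preparation included, would give such agreement, so it does not tell these apart. Blocking the split kept 93.7% of calls and decides nothing, as the block moves no log2 change. Lost 5' signal on the bam arrays stays open for the risen genes, whose second probe sets showed a median of 0.6 of the first's change (95% bootstrap interval 0.13 to 1.02; 0.21 for fallen genes). For fallen genes, with a median of -0.64, the lowest 3' or middle control change was -0.15 (95% interval down to -0.42). On the scale of the fit it was -0.25 (down to -0.39). Of the falls, 84.3% lay beyond -0.42, but passing the threshold already favours large falls. The actin, eIF-4a and GAPDH controls also do not show how far other transcripts moved. The interval for the second probe sets of fallen genes was -0.03 to 0.56, and 57.8% of these sets changed in the same direction. Lost 5' signal and other differences in RNA preparation therefore stay open for the fallen genes too.

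The second pattern is the rise of Bom peptide, Drs, Tsf1 and muscle genes. Of these 9 genes 7 were highest on stwl bam replicate 1, against 30.2% of other risen genes (permutation p = 0.0073, with the array picked anew in each of 10000 permutations). The 9 genes were grouped after their values were seen. The permutation treats genes as independent, while the Bom genes shared 1 profile, so this p is too small. The gene up was level on replicates 1 and 3, at 11.62. The other 15 fat body genes had a median log2 change of -0.25 (95% bootstrap interval -0.56 to 0.68). Called among them were the risen Obp99c and apolpp and the fallen NLaz, so this median does not show that a fat body rise is missing. Of 22 muscle genes 8 rose and 4 fell, with a median log2 change of 0.12, Act88F and up included. Members of both lists went both ways, so muscle and fat body tissue in the stwl bam samples may still account for part of the rise. A change caused by genotype was not tested apart from such tissue.

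The third pattern is the low signal of vitelline membrane and yolk protein genes on stwl bam replicates 1 and 3 only. On 2016 genes called without stwl bam replicate 2, that array lay at a median of 0.87 of the way from the bam mean to the other stwl bam arrays (95% bootstrap interval 0.85 to 0.89), which argues against a bam sample under its label. On the 594 of these with at least a 2-fold change, the set computed first, the position was 0.72. Picking genes on the other arrays lowers the position of the array left out, and no other array was placed in this way. A partial mixture is therefore neither shown nor excluded. A differing share of late-stage follicle cells may account for it. Of the eggshell genes whose values had not been seen beforehand, 50% (3 of 6) had the order replicate 2, 3, 1, as did 10 of the 12 seen. The one-sided exact binomial p was 0.0623, with chance set at 1 in 6 and genes treated as independent. All 18 members were higher on replicate 2 than on the other stwl bam arrays, which had prompted the test. Given that, chance for the order is 1 in 2, so the test decides nothing, and 6 genes are too few. No biological explanation was tested, as the design sets none between samples of 1 genotype.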

How the results depend on the processing

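The alternatives named in the methods as added were chosen after seeing the data. With 974 higher and 1142 lower genes as reported, limma's counts stayed within 1.5 times under the other normalizations, offsets, filters, prior, array weights and probe set rule. They moved to 454 and 473 with a plain test of each probe set that shares no variance across genes, to 559 and 685 on replicates 2 and 3 only, to 265 and 194 with a 2-fold limit, and to 415 and 445 at an adjusted p under 0.01. Leaving out each array gave 516 to 1007 higher and 557 to 1223 lower genes. A stricter threshold lowers counts by construction, and the other moves were not tested further. With the replicate block, 884 higher and 1014 lower genes were called and stwl stayed at -0.31. Deviations of same-numbered samples correlated at -0.051, -0.043 and 0.011 and none was best with its own number. These values show no pairing by number but cannot exclude one, as spike-in signal was lower on replicate 1 of both genotypes. The stwl change ran from -0.46 to -0.10 without single arrays and passed under none of the settings run. The number of called lists, 1 as reported, was 2 with intensities as deposited, median centring and rescaling to 1 trimmed mean, 0 with estimated correlation, and 0 to 1 without single arrays. Of 2104 other values of named genes 281 lost their call, 5 gained one and 0 turned. Of 522 list results 3 lost and 4 gained a call. Signal over background limits dim genes: those below it on all arrays of a genotype have only bounds, and those named with part of their arrays below it are given with the number.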

Other observations

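The X chromosome and gene length were looked at only after the main results were seen. Of 1447 tested X-linked genes (Release 6 assembly) 216, or 14.9%, were higher in stwl bam, against 10.4% of genes elsewhere. Fisher's exact test gave an odds ratio of 1.52 and an adjusted p of 1.36e-05 over 12 chromosome tests, treating genes as independent. The share was larger on the X in each of 5 groups of genes by length, with a joint odds ratio of 1.64. It was also larger under 3 other normalizations and without each array in turn, with odds ratios from 1.42 to 1.66. On chromosome 4, 15 of 60 genes were lower, or 25%, against 12.9% elsewhere (adjusted p = 0.0428, Fisher's exact test). On chromosome 2R 9.4% of genes were higher, against 11.6% elsewhere, at the same adjusted p in Fisher's exact test. Unlike the X, chromosomes 4 and 2R were not examined by gene length, under other normalizations or without single arrays. In the longest of 5 length groups over all chromosomes 23.1% of genes were lower. The median log2 change was -0.015 on the X and from -0.025 to -0.095 on the other chromosomes, so the X as a whole did not rise. The sex determination list held msl-2 and mof among the fallen genes, but a link between them and the X was not tested.

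Longer genes tended to be lower in stwl bam, though most genes of every length group passed in neither direction. Across 8725 genes, which are not independent replicates, Spearman's rho of log2 change with genomic length was -0.264. In the shortest of 5 equal groups of genes 16.6% were higher and 3.8% lower, and in the longest 6.8% were higher and 23.1% lower. For 109 fallen genes with a further probe set, that set changed in the same direction in 57.8% and was called so in 18.3%. For 13 of them limma called it in the opposite direction. For 57 risen genes with a further probe set these values were 71.9%, 31.6% and 2.

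Among piRNA pathway genes outside the naming rule, picked after their values were seen, piwi was at 0.40 and rhi at -0.43, both past the limma threshold.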
